A study of Mus musculus with 24 samples.

How the data were processed

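RNA was measured in 24 libraries of whole cochlea from CBA/Sca mice aged 12 weeks. Per the labels the libraries fall into 8 groups of 3, which cross noise or sham exposure, day or night, and adrenalectomy (ADX) or sham operation. The libraries were stranded, made from 300 ng of RNA with poly-A selection, pooled by 6 and sequenced as 50-base single reads. The deposited table holds raw counts of reads per gene symbol, which the authors made before any normalisation. The submitters' notes name TopHat2 2.0.11, HTSeq 0.6p1 and the genome build mm10, with neither a gene annotation nor the strand setting of the counting. Whether the counting separated the reads of a gene from those of a neighbour on the opposite strand is therefore unknown.

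The table had 23420 entries, of which 3340 had no count in any library. A spreadsheet had turned 27 names into dates, with 2 of these names on 2 entries each. These entries held 0.214% of all counts and were kept as unidentified. Gene positions were taken from GENCODE vM21 (GRCm38) by symbol, which matched 21751 entries.

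The total per library ran from 18894996 counts in day sham exposure sham-operated a to 36108962 in day noise ADX b. The 10 most counted genes took between 3.36% and 4.89% of a library. No library repeated another: over the 24 pairs of libraries within a group, the chi-square per gene ran from 6.1 to 41.4 among genes with a summed count of at least 20.

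Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 8 groups, which left 16607 genes. TMM factors ran from 0.974 to 1.02. A model with 1 coefficient per group was fitted to all 24 libraries by quasi-likelihood with a robust estimate of the spread, and 14 contrasts were tested with two-sided quasi-likelihood F-tests. The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.0991. Log2 values per library used a prior count of 2. Levels are given in CPM, the counts scaled by edgeR to a common library size with the TMM factors, as mean ± SD over 3 libraries, and log2 fold changes with their standard error (SE).

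The genes named for each comparison follow a rule with 4 parts, and not every gene that the rule takes is named. The first takes up to 8 genes per direction with the largest change among those past the threshold with a mean log2 CPM of at least 0. For a comparison of a pair of groups all 3 libraries of one group had to lie above all 3 of the other, and members of the neutrophil, lymphoid, erythroid and muscle lists were left out. The second takes up to 15 members of the gene lists past the threshold, by the smallest adjusted p. The third is 12 fixed genes: Per1, Per2, Nr1d1, Dbp, Arntl, Fkbp5, Tsc22d3, Sgk1, Fos, Ccl2, Il6 and Bdnf, of which Il6 did not pass the filter. The fourth takes up to 2 members with the largest change from each list described. Other members of a list that are named where its calls are counted, and genes shared between comparisons, were chosen after their values were seen.

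The 24 gene lists held 318 entries, of which 314 had an entry in the table, 4 of them under an older symbol (Ciart, Adgre1, Hbb-bs and Epb42). The other entries (Ly6g, Ighm, Hbb-bt and Ahsp) were left out. The process lists were clock genes high at dusk, clock genes high at dawn, glucocorticoid-induced genes, immediate early genes, chemokines and cytokines, NF-kB and acute-phase genes, interferon-stimulated genes, heat-shock and chaperone genes, oxidative stress response genes, neurotrophins and their receptors, and cell cycle genes. The marker lists were those of hair cells, supporting cells, spiral ganglion neurons, glia and myelin, stria vascularis, spiral ligament fibrocytes, bone, endothelium, macrophages, neutrophils and myeloid marrow, lymphoid cells, erythroid cells and skeletal muscle. Some genes stand on several lists (Per1, Dusp1 and Nfkbia among them). Each list was tested against the other genes with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and beside it with a correlation estimated from the data, adjusted over the lists within a comparison.

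The groups, the contrasts, the model, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is named as made afterwards. The alternatives chosen at that point were RLE size factors, the Wald test of DESeq2 1.42.0, limma voom with library weights, no filter on low counts, a fit of only the groups compared, a replicate block that joins libraries of the same letter, and leaving out each library in turn. For the lists they were the estimated correlation, the block and RLE factors. Chosen after seeing the data were a fit without 3 libraries that held pituitary or cerebellar transcripts, the effect of adrenalectomy among noise-exposed libraries and the effect of time among noise-exposed sham-operated libraries. Shared letters were checked as pairs by correlating residuals: 5 of the 24 pairs of libraries with 1 letter had r above 0.1, over a range of -0.264 to 0.41. All 5 lay among the 6 pairs of the noise comparisons in sham-operated mice, and 16 of 24 libraries correlated best with their own letter. The model without pairs was kept, and the block was run beside it. With the replicate block the noise comparison by day in sham-operated mice, where all 3 pairs lay above 0.1, gave 40 genes against 41 without it.

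The pipeline was tested on simulated data in which 200 of 16509 genes had been changed. For the noise effect at night in sham-operated mice it recovered 65.2% of the changes of 1.5-fold, 76.1% of those of 2-fold and 98.5% of those of 4-fold, and 9.66% of its calls were false. For noise by time in sham-operated mice these shares were 42.4%, 70.1% and 95.5%, with 4.83% false calls. For noise by time by surgery they were 24.2%, 53.7% and 84.8%, with 3.57% false calls. With no gene changed the pipeline made 0 false calls by edgeR in 16510 genes. The simulated genes were drawn independently of one another, without transcripts of other tissues. In the real data the median correlation estimated within a list was 0.394 over the tests of a difference, so these shares may not hold there.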

Results

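Messenger RNA of whole cochleae was counted per gene in 24 libraries, 3 from each of 8 groups of mice. Mice had been adrenalectomized (ADX), which removes the main source of glucocorticoid hormone, or sham-operated. They were then exposed to noise of 6 to 12 kHz at 100 dB SPL for 1 h, or to a sham exposure, starting 3 h after lights-on (day, ZT3) or 15 h after it (night, ZT15). The series design states collection 2 h after the noise, which implies ZT6 and ZT18, whereas the sample labels give ZT11 and ZT23. Neither source resolves this conflict. The totals ran from 18894996 to 36108962 counts per library. The labels do not say that the libraries come from separate animals. If they do not, the p-values measure no more than the spread between these samples. Positions are given for GRCm38.

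Genes typical of the pituitary or the cerebellum stood out most in 3 libraries. In night noise ADX a the pituitary hormone genes Gh, Prl and Pomc reached 7590, 1580 and 465 CPM and took 0.947% of the counts. Gh measured 0.576 to 41.9 CPM in the 21 libraries outside the night noise ADX group. Night noise ADX c held less of the 3 genes, at 61.4, 21.8 and 49.4 CPM, but each value lay above those 21 libraries. It stayed in the fit that left out 3 libraries. Of 8 cerebellar genes, 8 had their 2 highest values in day sham exposure sham-operated b and night noise sham-operated b, where Cbln3, a gene of cerebellar granule cells, reached 38.5 and 33.3 CPM. The lists of pituitary and cerebellar genes were written after the data were seen.

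The first question was how the cochlea of sham-operated mice responded to noise by day. Rises in single genes passed the threshold, while 0 of the 24 gene lists passed with an estimated correlation. Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477273), rose 4.37-fold, from 10 ± 2.54 to 44.2 ± 20.6 CPM (SD, n = 3). Gem, a small GTPase that restrains calcium channels (chromosome 4, 11704457 to 11714752), rose 5.64-fold. Gdf15, a stress-induced cytokine (chromosome 8, 70629393 to 70632456), rose from 0.95 ± 0.321 to 4.6 ± 1.53 CPM, and Ccl2, a chemokine that draws monocytes (chromosome 11, 82035571 to 82037453), rose from 0.441 ± 0.161 to 2.39 ± 0.969 CPM. Falls were smaller, as in Ankrd23, an ankyrin-repeat protein (chromosome 1, 36530188 to 36536883; 29 ± 3.26 to 17.2 ± 1.83 CPM).

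Of the 22 immediate early genes tested, 7 rose and 0 fell (18 and 0 adjusted over the list alone), and 15 did not pass; their median log2 change was 0.868. Fosl1, another AP-1 subunit, had the largest change of the list, 4.27 (SE 0.503, adjusted p = 0.000136), followed by Fosb at 2.88 (SE 0.532, adjusted p = 0.0168), and Atf3, Maff, Egr2 and Cyr61 rose as well. Among 19 chemokines and cytokines, 3 rose (4 adjusted over the list alone): Ccl7 by 2.59, Ccl2 by 2.39 (SE 0.401, adjusted p = 0.00486) and Lif, a cytokine of the interleukin 6 family, by 1.81. Srxn1, which repairs oxidised peroxiredoxins, was the 1 of 12 oxidative stress genes that rose, by 0.71. The glucocorticoid-induced genes Sgk1 and Pdk4 rose by 0.70 and 0.90, and the other 22 of that list did not pass (4 rose and 1 fell adjusted over the list alone). Falls reached Rab17 (-0.705), a GTPase of epithelial trafficking, Gm20554 (-0.57), Sox8 (-0.49), Sorl1 (-0.30) and Syne2 (-0.29). Changes in Per1, Per2, Nr1d1, Dbp, Arntl, Fkbp5, Tsc22d3 and Bdnf did not pass, with adjusted p from 0.717 for Per1 to 0.995 for Tsc22d3.

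By camera with the preset correlation the immediate early genes had an adjusted p of 2.02e-25 (adjusted p = 0.142 with an estimated correlation) and the chemokines one of 0.00143 (adjusted p = 0.307 with an estimated correlation). Markers of glia and myelin (median 0.304, 0 past the threshold) gave 0.000378, spiral ganglion neuron markers (median 0.297) 3.11e-06, bone markers (median 0.271) 0.00143 and neutrophil markers (median -0.201) 0.00347. With an estimated correlation their adjusted p was 0.502, 0.307, 0.532 and 0.647, and 0 of the 24 lists passed in this comparison, where 9 had passed with the preset one. In all, edgeR called 41 genes, 35 higher and 6 lower, of 16607 tested. The count was 25 without day noise sham-operated b, 27 without day noise sham-operated c, 27 without day sham exposure sham-operated a or b, and 23 without day sham exposure sham-operated c. Fos passed in 1 of these 6 fits, with an adjusted p of up to 0.213 without day noise sham-operated b, Ccl2 in 5 and Sgk1 in 2. Gem, Gdf15, Fosl1, Lif, Maff, Atf3, Pdk4, Srxn1 and Ankrd23 passed in all 6.

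**Figure D1:**
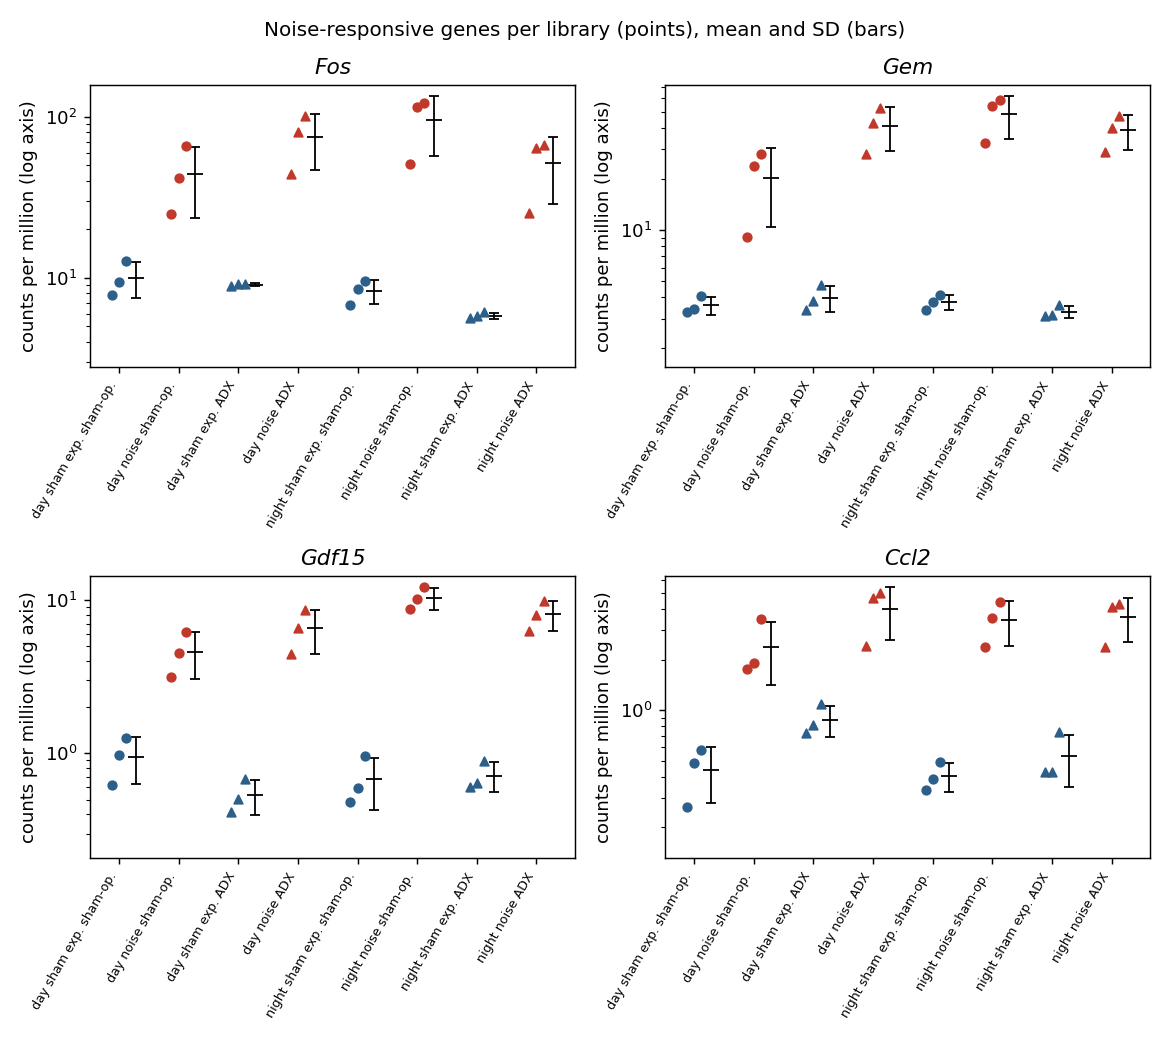
CPM (log axis) of Fos, Gem, Gdf15 and Ccl2 in each library of the 8 groups, with red for noise, blue for sham exposure, circles for sham-operated and triangles for ADX, and bars for the mean and SD of 3 libraries. In each pair of groups the noise-exposed mean lies above the unexposed one, as for Gdf15 at night in sham-operated mice (10.3 ± 1.69 against 0.682 ± 0.253).

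At night the same question was asked of sham-operated mice exposed during their active phase. Fos rose 11.5-fold, from 8.31 ± 1.45 to 95.8 ± 38.9 CPM (SD, n = 3), Gem 12.8-fold, from 3.77 ± 0.385 to 48.3 ± 13.6 CPM, and Gdf15 15.1-fold. The orphan nuclear receptors Nr4a3 and Nr4a1, which are induced within hours of a stimulus, rose 10.6-fold and 8.47-fold. Ccl2 rose from 0.404 ± 0.0811 to 3.44 ± 1.02 CPM. Rab17 fell from 12.4 ± 1.11 to 6.62 ± 1.2 CPM.

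Of the 22 immediate early genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 1.58; the other 4 did not pass. Fosl1 changed by 5.53 (SE 0.492, adjusted p = 6.81e-07) from a level at which 1 of the unexposed libraries had 0 counts, so its fold is uncertain, and Fosb by 3.82 (SE 0.523, adjusted p = 0.000282). Among the chemokines and cytokines 4 of 19 rose (7 adjusted over the list alone), with Ccl7 at 4.14, Ccl2 at 3.07, Cxcl1 at 2.63 and Lif at 1.28. The NF-kB and acute-phase list had 2 rises of 20 (7 adjusted over the list alone): Ptgs2, the inducible cyclooxygenase, by 1.94 and Socs3, a brake on cytokine signalling, by 1.39. Srxn1 rose by 0.61, alone among the oxidative stress genes. Glucocorticoid-induced genes had 4 rises of 24 (8 adjusted over the list alone), namely Dusp1 by 1.78, Sgk1 by 0.93, Pdk4 by 0.92 and Errfi1 by 0.73. Nr1d1, a repressor of the circadian clock, rose from 23.2 ± 1.53 to 38.8 ± 3.89 CPM (log2 change 0.74, adjusted p = 0.0204). Falls were Rab17 (-0.91), Ankrd23 (-0.63), Klhdc7a (-0.58), Grm7 (-0.57), Plekha6 (-0.40), Rab11fip4 (-0.35), Map3k9 (-0.31) and Clasp1 (-0.18). Changes in Per1, Per2, Dbp, Arntl, Fkbp5, Tsc22d3 and Bdnf did not pass, with log2 changes from -0.27 for Arntl to 0.34 for Dbp.

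The preset camera test gave the immediate early genes an adjusted p of 7.96e-51 (adjusted p = 0.0022 with an estimated correlation), the chemokines 7.2e-13 (adjusted p = 0.00238 with an estimated correlation), the NF-kB list 3.19e-13 (adjusted p = 0.0244 with an estimated correlation) and the oxidative stress list 0.00549 (adjusted p = 0.0257 with an estimated correlation). These 4 lists of the 11 that passed with the preset correlation also passed with the estimated one. Bone markers (median 0.222), spiral ganglion neuron markers (-0.246), macrophage markers (0.192) and interferon-stimulated genes (0.226) had 0 genes past the threshold. Endothelial markers (median 0.103, adjusted p = 0.0557), hair cell markers (-0.11, adjusted p = 0.0516) and stria vascularis markers (-0.0839, adjusted p = 0.111) did not pass as lists. Of 119 genes called by edgeR, 111 were higher and 8 lower. Without night noise sham-operated b, 1 of the libraries with cerebellar transcripts, the count was 78. Nr1d1 passed in 1 of the 6 fits without 1 library, with an adjusted p of up to 0.113 without night sham exposure sham-operated a, and Fos, Ccl2, Fosl1 and Sgk1 passed in all 6.

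The third comparison asked how libraries labelled ADX differed between noise and sham exposure by day. The mean of the glucocorticoid-induced genes, in log2 CPM centred over all libraries, was 0.262, 0.169 and 0.196 in the day noise ADX libraries. It was -0.543 to -0.471 in day sham exposure ADX and -0.137 to 0.275 in day noise sham-operated. Of the genes named for noise in sham-operated mice, Fos rose from 9.06 ± 0.187 to 75.1 ± 28.4 CPM (SD, n = 3), Gem rose from 3.98 ± 0.699 to 41.2 ± 12.1 CPM and Gdf15 from 0.534 ± 0.137 to 6.51 ± 2.07 CPM. Sgk1, a kinase induced by glucocorticoid and by stress (chromosome 10, 21882184 to 21999903), rose 2.5-fold, from 115 ± 8.7 to 288 ± 23.6 CPM. The clock gene Per1 rose from 48.5 ± 2.56 to 119 ± 9.97 CPM. Bdnf, a neurotrophin of spiral ganglion neurons (chromosome 2, 109674700 to 109727007), fell from 3.33 ± 0.333 to 1.61 ± 0.283 CPM, and Rxfp3, the receptor of relaxin 3, fell from 7.33 ± 1.76 to 2.16 ± 0.99 CPM.

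Of 22 immediate early genes 19 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.22. The largest changes were Fosl1 at 4.83 (SE 0.456, adjusted p = 1.74e-06) and Nr4a3 at 3.745 (SE 0.531, adjusted p = 0.000423). Ccl7, Ccl2 and Lif rose by 3.58, 2.21 and 2.14 among 19 chemokines and cytokines (9 adjusted over the list alone). Of 20 NF-kB and acute-phase genes 5 rose (9 adjusted over the list alone): Socs3 by 1.28, Sele by 0.91, Vcam1 by 0.54, Osmr by 0.45 and Nfkbia by 0.45. Of 24 glucocorticoid-induced genes 9 rose and 0 fell (20 and 0 adjusted over the list alone), among them Sgk1 by 1.32, Per1 by 1.30, Ddit4 by 1.11 and Errfi1 by 1.06. Fkbp5, a chaperone of the glucocorticoid receptor, had a log2 change of 0.87 (SE 0.318, adjusted p = 0.117) and Hif3a one of 1.84 (adjusted p = 0.0752), neither past the threshold. Fkbp5 measured 61.7 ± 6.13 CPM in the day noise ADX libraries, close to the 62.5 ± 21.7 CPM of day noise sham-operated and above the 33.8 ± 2.87 CPM of day sham exposure ADX.

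In the same comparison 2 of 12 clock genes high at dusk rose (Per1 and Nr1d1) and 3 fell (Per3 at -0.75, Hlf at -0.47 and Tef at -0.41), with 3 and 4 adjusted over the list alone. Among the clock genes high at dawn Nfil3 rose by 0.53. Macrophage markers had 4 rises of 10 (8 adjusted over the list alone): Aif1 by 0.65 and the complement genes C1qb by 0.56, C1qc by 0.52 and C1qa by 0.47. The bone markers Acp5 and Dmp1 rose by 0.80 and 0.68, and the chaperone Hspb1 rose by 0.84. The supporting cell gene Lfng rose by 0.41 and Otogl fell, at -0.52. The hair cell gene Chrna10, an acetylcholine receptor subunit, fell, at -0.75. Srxn1 and Gclc, which makes glutathione, rose by 0.65 and 0.32. Other falls were 4933413G19Rik (-1.64), Xirp2 (-1.58), Tmem200c (-1.49), Cyp4f14 (-1.31), Gbp11 (-1.31) and Dio3os (-1.23). Bdnf was the 1 of 11 neurotrophins and their receptors that passed (1 lower adjusted over the list alone; median 0.0461, mean -0.0394). Per2, Dbp, Arntl and Tsc22d3 did not pass. Neutrophil (median 0.339), erythroid (0.457) and cell cycle (0.251) lists had 0 genes past the threshold, against 5, 4 and 0 adjusted over the list alone, and skeletal muscle markers, of which Xirp2 is no member, had a median of -2.25 with 0 calls.

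By camera the preset adjusted p was 1.82e-26 for immediate early genes (adjusted p = 0.0439 with an estimated correlation), 1.58e-06 for chemokines (adjusted p = 0.0439 with an estimated correlation), 1.18e-15 for glucocorticoid-induced genes (adjusted p = 0.061 with an estimated correlation), 4.55e-08 for the NF-kB list (adjusted p = 0.111 with an estimated correlation) and 0.00327 for the oxidative stress list (adjusted p = 0.0439 with an estimated correlation). The other lists of the 13 that passed with the preset correlation did not pass with the estimated one, where 3 lists did. The edgeR count was 667 genes, 334 higher and 333 lower, and it moved with each library of the 6. It was 2254 without day noise ADX a, 205 without day noise ADX b, 144 without day noise ADX c, 196 without day sham exposure ADX a, 302 without day sham exposure ADX b and 208 without day sham exposure ADX c. Per1, Fos, Ccl2 and Sgk1 passed in all 6 fits. Bdnf passed in 1, with an adjusted p of up to 0.132 without day noise ADX c, and Nr1d1 in 3, with one of up to 0.0761 without day sham exposure ADX a.

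At night the libraries labelled ADX again had Fos, Gem and Gdf15 among their largest rises with noise. Fos went from 5.84 ± 0.251 to 51.8 ± 23.1 CPM (SD, n = 3), Gem from 3.29 ± 0.26 to 38.7 ± 9.03 CPM, and Gdf15 from 0.715 ± 0.158 to 8.03 ± 1.79 CPM. Ccl2 rose 6.75-fold and Sgk1 2.1-fold. The largest fitted changes belonged to Prl (9.66, adjusted p = 0.0401) and Dlk1 (6.16, adjusted p = 0.0448), and both rest on the pituitary transcripts of night noise ADX a: without that library their adjusted p was 0.279 and 0.688.

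Of 22 immediate early genes 12 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.10, led by Fosl1 at 5.525 (adjusted p = 1.23e-06) and Fos at 3.15 (SE 0.441, adjusted p = 0.000745). Ccl7 by 3.53, Ccl2 by 2.755 and Lif by 1.30 were the 3 of 19 chemokines and cytokines that rose (3 adjusted over the list alone). Socs3 rose by 1.095 in the NF-kB list (3 adjusted over the list alone), and Srxn1 by 0.74 among oxidative stress genes. Of 24 glucocorticoid-induced genes 4 rose (10 adjusted over the list alone), namely Dusp1 by 1.66, Sgk1 by 1.07, Pdk4 by 0.81 and Errfi1 by 0.80. Library a of night noise ADX stood apart in this list, with a mean centred log2 CPM of 0.466 against -0.174 in b, -0.449 in c and -0.588 to -0.315 in night sham exposure ADX. Without it these 4 genes still passed, with adjusted p from 0.000169 for Sgk1 to 0.0396 for Errfi1. Klhdc7a (-0.63), Wdr86 (-0.57), Sox8 (-0.52), Hspg2 (-0.40), Rftn2 (-0.37), Gas7 (-0.34), Tnrc18 (-0.32) and Plxnd1 (-0.30) fell. Per1, Per2, Nr1d1, Dbp, Arntl, Fkbp5, Tsc22d3 and Bdnf did not pass, with adjusted p from 0.232 for Dbp to 0.927 for Per2.

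Preset camera gave the immediate early genes an adjusted p of 5.21e-29 (adjusted p = 0.0424 with an estimated correlation), the chemokines 2.2e-06 (adjusted p = 0.0424 with an estimated correlation), the oxidative stress list 0.00372 (adjusted p = 0.0424 with an estimated correlation), the glucocorticoid-induced genes 3.45e-13 (adjusted p = 0.0969 with an estimated correlation) and the NF-kB list 0.00054 (adjusted p = 0.445 with an estimated correlation). Interferon-stimulated genes (median -0.225) and bone markers (-0.223) had 0 genes past the threshold. The count by edgeR was 83 genes, 72 higher and 11 lower. It was 50 without night noise ADX a, 134 without night noise ADX c, 48 without night sham exposure ADX a and 37 without night sham exposure ADX c. Fos, Ccl2, Fosl1 and Sgk1 passed in all 6 fits without 1 library, Fosb in 2, and Nr4a3 had an adjusted p of up to 0.0698 without night sham exposure ADX c.

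The 4 noise comparisons share no library, and 25 genes rose in each of them. Besides Fos, Fosb, Fosl1, Gem, Gdf15, Ccl2, Ccl7, Lif, Maff, Atf3, Sgk1, Srxn1, Pdk4 and Cyr61, they included Hbegf, a growth factor of the EGF family, Tnfrsf12a, the receptor of the cytokine TWEAK, Sprr1a, a protein of stressed and regenerating cells, Apold1, Dusp4, Flnc, Ifrd1, Medag, Nab2 and Pvr. Of the rises in sham-operated mice 31 were shared by day and night, against 0.234 if the comparisons were independent (Fisher's exact p = 1.93e-65), and 80 of those at night were shared with ADX mice by day, against 2.23 (Fisher's exact p = 1.41e-113). Genes are not independent of one another, so these p-values are too small. In all 723 genes were called in at least 1 noise comparison, 571 of them by day in ADX alone.

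Whether the response to noise differed between night and day in sham-operated mice was tested as a difference of the effects. For Fos, Gem and Gdf15 the fitted changes were larger at night, but their differences did not pass the threshold, and the same held for Ccl2. Immediate early genes had a median difference of 0.709 with 0 of 22 past the threshold (3 higher and 1 lower adjusted over the list alone). The preset camera test gave 1.61e-07 (adjusted p = 0.673 with an estimated correlation). Spiral ganglion neuron markers had a median of -0.488, 0 of 12 past the threshold and 6 lower adjusted over the list alone, with a preset adjusted p of 1.31e-07 (adjusted p = 0.404 with an estimated correlation). NF-kB genes differed by a median of 0.233 (2 adjusted over the list alone). The count of genes was 0 by edgeR, where the smallest adjusted p was 0.192 and 1213 genes lay at an unadjusted p under 0.05, against 20 by DESeq2 and 14 by limma voom with library weights. Leaving out any 1 library gave 0 as well.

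In ADX mice the same difference singled out Khdrbs3, a regulator of splicing (chromosome 15, 68928420 to 69101211). It fell with noise by day, from 20.2 ± 0.82 to 16.2 ± 0.921 CPM (SD, n = 3), and rose with noise at night, from 18.6 ± 0.323 to 22.7 ± 0.828 CPM. The log2 difference was 0.60 (SE 0.086, adjusted p = 0.0103). For Fos, Gem, Gdf15, Ccl2 and Sgk1 the difference did not pass. Macrophage markers (median -0.282), bone markers (-0.399; 1 lower adjusted over the list alone) and hair cell markers (0.421) had 0 genes past the threshold. Their preset adjusted p was 0.00075, 0.000834 and 0.00113, each with adjusted p = 0.56 with an estimated correlation. Khdrbs3 was the 1 gene called by edgeR. A fit of only the groups compared called 0 genes, as did the fit without the 3 libraries that held pituitary or cerebellar transcripts. The count was 36 without day noise ADX a, 3 without night noise ADX a, 2 without night noise ADX b and 0 without day noise ADX b, day sham exposure ADX a, night sham exposure ADX b or night sham exposure ADX c. Without the last of these the adjusted p of Khdrbs3 was 0.0642, and it was at most 0.076 over the 12 fits.

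The next comparison asked whether the response to noise by day differed between libraries labelled ADX and sham-operated, and it rests on the same day noise ADX libraries. Glucocorticoid-induced genes had a median difference of 0.495, higher in ADX, with 0 of 24 past the threshold and 8 higher adjusted over the list alone. Preset camera gave them an adjusted p of 1.37e-10 (adjusted p = 0.412 with an estimated correlation). Neutrophil markers (median 0.595; 5 adjusted over the list alone), macrophage markers (0.451; 6 adjusted over the list alone) and heat-shock genes (0.384; 1 adjusted over the list alone) lay higher, and glia and myelin markers (-0.557; 3 lower adjusted over the list alone) lay lower. Each of these had 0 genes past the threshold over all genes and an adjusted p of 0.412 with an estimated correlation. The count by edgeR was 0, with 2716 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.155. DESeq2 called 158 and limma voom with library weights 291. Without day noise ADX a edgeR called 811 genes, 366 higher and 445 lower, and without day noise sham-operated a it called 1.

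For the response at night, surgery made no difference that passed for Fos, Gem, Gdf15 or Ccl2. Bone markers (median -0.483; 3 lower adjusted over the list alone) and interferon-stimulated genes (-0.451; 1 lower adjusted over the list alone) had 0 genes past the threshold and preset adjusted p of 1.59e-07 and 2.13e-07 (adjusted p = 0.251 and 0.402 with an estimated correlation). Lymphoid markers had a median of -0.439 but a mean of 0.00491. The 6 clock genes high at dawn had a median of 0.335 with 0 past the threshold (1 higher adjusted over the list alone; preset 9.44e-05, adjusted p = 0.0603 with an estimated correlation). The count by edgeR was 0, with 1056 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.336. DESeq2 called 4 and limma voom with library weights 0.

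Noise by time by surgery asked whether the day and night difference in the response depended on the adrenal glands. Immediate early genes had a median of -0.825 with 0 of 22 past the threshold (1 higher and 3 lower adjusted over the list alone) and a preset adjusted p of 1.83e-06 (adjusted p = 0.418 with an estimated correlation). Spiral ganglion neuron markers had a median of 0.893 with 0 of 12 past the threshold (7 higher and 1 lower adjusted over the list alone), with the same adjusted p in both tests. The count by edgeR was 0, with 2162 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0973. DESeq2 called 197 and limma voom with library weights 575. By edgeR the count was 554 without day noise ADX a, 124 without night sham exposure sham-operated a and 1 without night noise ADX c. Over the comparisons that test a difference, 66 of 144 pairs of list and comparison passed with the preset correlation and 0 with an estimated one, whose median was 0.394.

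The effect of time of day was measured in unexposed sham-operated mice. Nr1d1 (chromosome 11, 98767932 to 98775333) was lower at night, 23.2 ± 1.53 against 132 ± 10.2 CPM (SD, n = 3), a fold of 0.177. Per2, a repressor of the clock (chromosome 1, 91415982 to 91459324), was higher at night, 109 ± 16.3 against 40.8 ± 6.04 CPM, and Cry1, its partner (chromosome 10, 85131700 to 85185064), was higher too, 36.2 ± 2.77 against 17.3 ± 2.2 CPM. Npas2, an activator of the clock (chromosome 1, 39193731 to 39363236), was lower, 7.03 ± 0.568 against 14.7 ± 2.67 CPM.

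Of 12 clock genes high at dusk Per2 rose by 1.42 and Nr1d1 and Dbp fell (-2.50 and -0.84), with 4 and 2 adjusted over the list alone. Among the clock genes high at dawn Cry1 rose by 1.07 and Npas2 fell (-1.06), with 3 rises and 2 falls of 6 adjusted over the list alone. Both clock lists had members that moved in opposite directions, and their preset adjusted p was 0.594 and 0.107 (adjusted p = 0.95 and 0.663 with an estimated correlation). Tubb3, a neuronal tubulin, rose by 0.67 among 12 spiral ganglion neuron markers, of which 10 rose adjusted over the list alone (median 0.426, preset 1.23e-07, adjusted p = 0.361 with an estimated correlation). The small heat-shock protein gene Cryab rose by 0.33 (3 of 14 adjusted over the list alone; preset 2.82e-05, adjusted p = 0.834 with an estimated correlation). Gm19522 rose by 2.03, Thbs4 by 1.02, Ppp1r1c by 1.01, Mamdc2 by 0.90 and Tmem200b by 0.84. Spon2 (-1.21), Lpl (-0.91), Gstm4 (-0.65), Fat2 (-0.64) and Hpgds (-0.63) fell. Per1, Arntl, Fkbp5, Tsc22d3, Sgk1, Fos and Bdnf did not pass, with adjusted p from 0.149 for Tsc22d3 to 0.916 for Bdnf.

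The edgeR count for time was 44 genes, 26 higher and 18 lower at night. With the replicate block it was 22, 12 higher and 10 lower. It was 15, 21 and 13 without day sham exposure sham-operated a, b and c, and 105, 6 and 8 without night sham exposure sham-operated a, b and c. Nr1d1, Cry1 and Gm19522 passed in all 6 fits. Per2 did not pass in 4 of them, with an adjusted p of up to 0.0955 without night sham exposure sham-operated c, Npas2 in 2, with one of up to 0.0664 without night sham exposure sham-operated b, and Dbp in all 6, with one of up to 0.209 without night sham exposure sham-operated c.

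**Figure D2:**
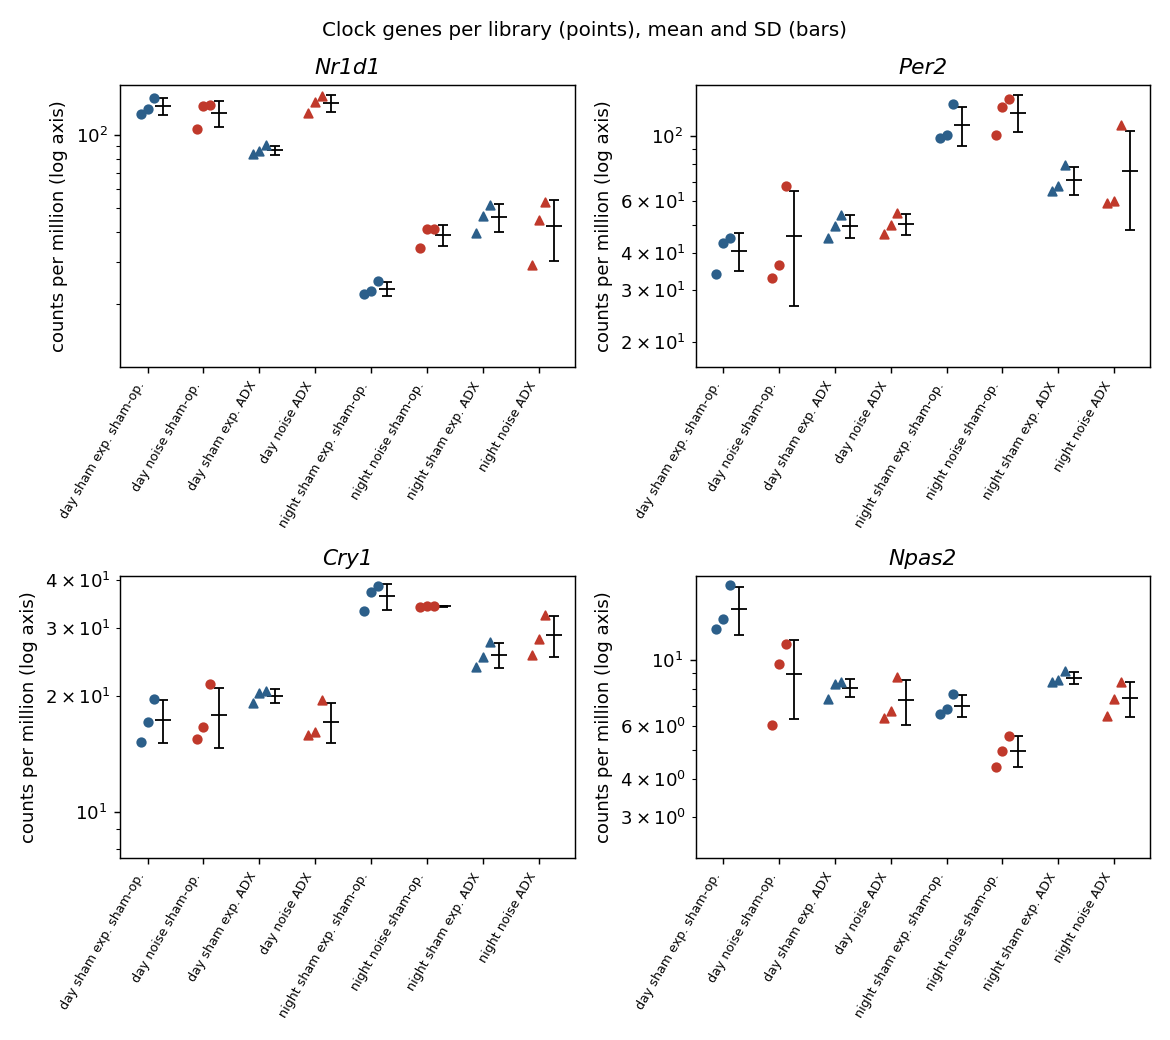
CPM (log axis) of the clock genes Nr1d1, Per2, Cry1 and Npas2 in each library of the 8 groups, coloured red for noise and blue for sham exposure, with circles for sham-operated, triangles for ADX, and bars for the mean and SD of 3 libraries. In unexposed sham-operated mice Nr1d1 and Npas2 lie lower, and Per2 and Cry1 higher, at night than by day.

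In unexposed ADX mice 3 genes differed between night and day, all lower at night. Nr1d1 measured 45.8 ± 6.09 against 86.8 ± 3.75 CPM (SD, n = 3), a log2 change of -0.92 (SE 0.147, adjusted p = 0.0328). Pla2g2d, a secreted phospholipase of immune cells (chromosome 4, 138775735 to 138782046), measured 2.52 ± 0.477 against 6.64 ± 1.52 CPM. Gdf6, a bone morphogenetic protein and spiral ligament marker (chromosome 4, 9844372 to 9862345), measured 11.5 ± 0.846 against 18.6 ± 1.88 CPM. Per2 (log2 change 0.52), Cry1 (0.35), Dbp (-0.55), Per1, Arntl and Fkbp5 did not pass. Nr1d1 was the 1 of 12 clock genes high at dusk that passed (0 rose and 2 fell adjusted over the list alone; median -0.0382, preset 0.0271, adjusted p = 0.683 with an estimated correlation). Bone markers had a median of 0.322 with 0 past the threshold (2 adjusted over the list alone; preset 1.1e-07, adjusted p = 0.221 with an estimated correlation), and skeletal muscle markers one of -2.14 (preset 0.000428, adjusted p = 0.683 with an estimated correlation). The edgeR count of 3 became 0 without day sham exposure ADX a, b or c, and 0 without night sham exposure ADX b or c. The adjusted p of Nr1d1 reached 0.345 without night sham exposure ADX b.

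Whether surgery changed the effect of time was tested in unexposed mice, and Nr1d1 was the 1 gene that passed. Its night-minus-day log2 change was smaller in size in ADX than in sham-operated mice (-0.92 against -2.50), a difference of 1.58 (SE 0.21, adjusted p = 0.0047). It passed in each of the 12 fits without 1 library, with an adjusted p of up to 0.0356 without night sham exposure sham-operated a. The differences in Per2, Cry1, Npas2 and Dbp did not pass. Spiral ganglion neuron markers had a median of -0.59 with 0 past the threshold and 9 of 12 lower adjusted over the list alone (preset 1.85e-10, adjusted p = 0.143 with an estimated correlation). Interferon-stimulated genes had one of 0.459 with 0 past the threshold (preset 6.71e-08, adjusted p = 0.42 with an estimated correlation). Without night sham exposure sham-operated a edgeR called 2 genes.

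Adrenalectomy by day in unexposed mice was compared to learn what loss of the adrenal glands did at rest. Rag2, which joins antigen receptor genes in precursor lymphocytes (chromosome 2, 101624718 to 101632529), was higher in ADX, 17.4 ± 2.16 against 8.09 ± 1.33 CPM (SD, n = 3), and Pkp1, a protein of desmosomes, was lower, 7.1 ± 1.24 against 16.4 ± 3.21 CPM.

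The clock gene Per3 rose by 0.83 (1 of 12 genes high at dusk; 3 rose and 2 fell adjusted over the list alone), Lef1 by 0.64, and Rnf149 fell (-0.45). Of 24 glucocorticoid-induced genes 0 passed and 15 fell adjusted over the list alone, with a median of -0.371 (preset 2.23e-15, adjusted p = 0.23 with an estimated correlation). Their changes included Hif3a at -1.845 (adjusted p = 0.223), Zbtb16 at -1.785 (adjusted p = 0.122) and Fkbp5 at -1.065 (SE 0.32, adjusted p = 0.201). Lymphoid markers had 0 of 11 past the threshold, 7 higher and 3 lower adjusted over the list alone and a median of 0.62 (preset 3.58e-05, adjusted p = 0.23 with an estimated correlation). Stria vascularis markers had 0 of 12 (1 lower adjusted over the list alone; median -0.16, preset 0.00168, adjusted p = 0.463 with an estimated correlation). Per1, Per2, Nr1d1, Dbp, Arntl, Tsc22d3, Sgk1 and Bdnf did not pass. The edgeR count was 7 genes, 4 higher and 3 lower. It was 0 without day sham exposure ADX a or b and 0 without day sham exposure sham-operated a or c, 13 without day sham exposure ADX c, and 30 without day sham exposure sham-operated b, the library with cerebellar transcripts. None of the 7 genes passed in all 6 fits.

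At night 8 of 24 glucocorticoid-induced genes were lower and 7 of 18 interferon-stimulated genes higher in ADX, and neither list passed with an estimated correlation (adjusted p = 0.0732 for both). None of the 28 named genes passed in all 6 fits without 1 library. Fkbp5 (chromosome 17, 28399094 to 28517527) was lower, 34.5 ± 8.5 against 96 ± 14.8 CPM (SD, n = 3). Hif3a, a hypoxia-inducible factor (chromosome 7, 17031507 to 17062427), was lower, 1.47 ± 0.243 against 7.97 ± 0.95 CPM, as was Lipg, the endothelial lipase (chromosome 18, 74939322 to 74961263), 2.03 ± 0.272 against 5.96 ± 0.278 CPM. Rag1, the partner of Rag2, was higher, 121 ± 28.3 against 52.3 ± 4.42 CPM, and Col2a1, a collagen of cartilage, was higher, 664 ± 181 against 277 ± 43 CPM.

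Of 24 glucocorticoid-induced genes 0 rose and 8 fell (0 and 17 adjusted over the list alone), with a median of -0.54 (preset 2.68e-16, adjusted p = 0.0732 with an estimated correlation). They were Hif3a (-2.44), Zbtb16 (-1.74), Plin4 (-1.65), Fkbp5 (-1.48, SE 0.318, adjusted p = 0.0267), Sult1a1 (-1.46), Tsc22d3 (-0.86), Mt2 (-0.80) and Arrdc2 (-0.71). Of 18 interferon-stimulated genes 7 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.679 (preset 1.73e-16, adjusted p = 0.0732 with an estimated correlation): Oasl2 by 1.24, Ifi44 by 1.19, Usp18 by 0.86, Gbp3 by 0.85, Bst2 by 0.62, Ddx58 by 0.42 and Stat2 by 0.37. Of 11 lymphoid markers 5 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.558, preset 0.002, adjusted p = 0.311 with an estimated correlation), with the B-cell genes Vpreb3 at 0.88 and Cd79b at 0.77 and the T-cell gene Cd3e at -2.28. Nr1d1 and Dbp rose by 0.98 and 0.76, and Cry1 fell (-0.50). Tectb, a protein of the tectorial membrane, fell (-1.18), and Car3, a carbonic anhydrase, rose by 0.75 as the 1 of 8 spiral ligament fibrocyte markers past the threshold.

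Outside the lists, 9030619P08Rik (1.515), Cyp4f14 (1.44), Cpz (1.39), Sstr1 (1.375), BC094916 (1.26) and Gbp10 (1.24) rose, and Nccrp1 (-2.04) and Fxyd2 (-1.605) fell. Hair cell markers had 0 of 14 past the threshold (0 and 4 adjusted over the list alone; median -0.291, preset 0.000126, adjusted p = 0.311 with an estimated correlation). Bone markers had 0 of 12 (8 and 1 adjusted over the list alone; median 0.507, preset 0.000127, adjusted p = 0.311 with an estimated correlation). Per1, Per2, Arntl, Sgk1, Fos and Bdnf did not pass, with adjusted p from 0.0614 for Sgk1 to 0.681 for Fos. The edgeR count was 263 genes, 185 higher and 78 lower. It was 61 without night sham exposure ADX a, 0 without night sham exposure ADX c, and 143, 1 and 0 without night sham exposure sham-operated a, b and c. Of the 28 named genes Lipg, Nccrp1, Nr1d1, Rag1, Vpreb3 and Gbp3 passed in 3. Whether the effect of adrenalectomy differed between night and day is the difference reported for time by surgery, in which Nr1d1 alone passed.

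**Figure D3:**
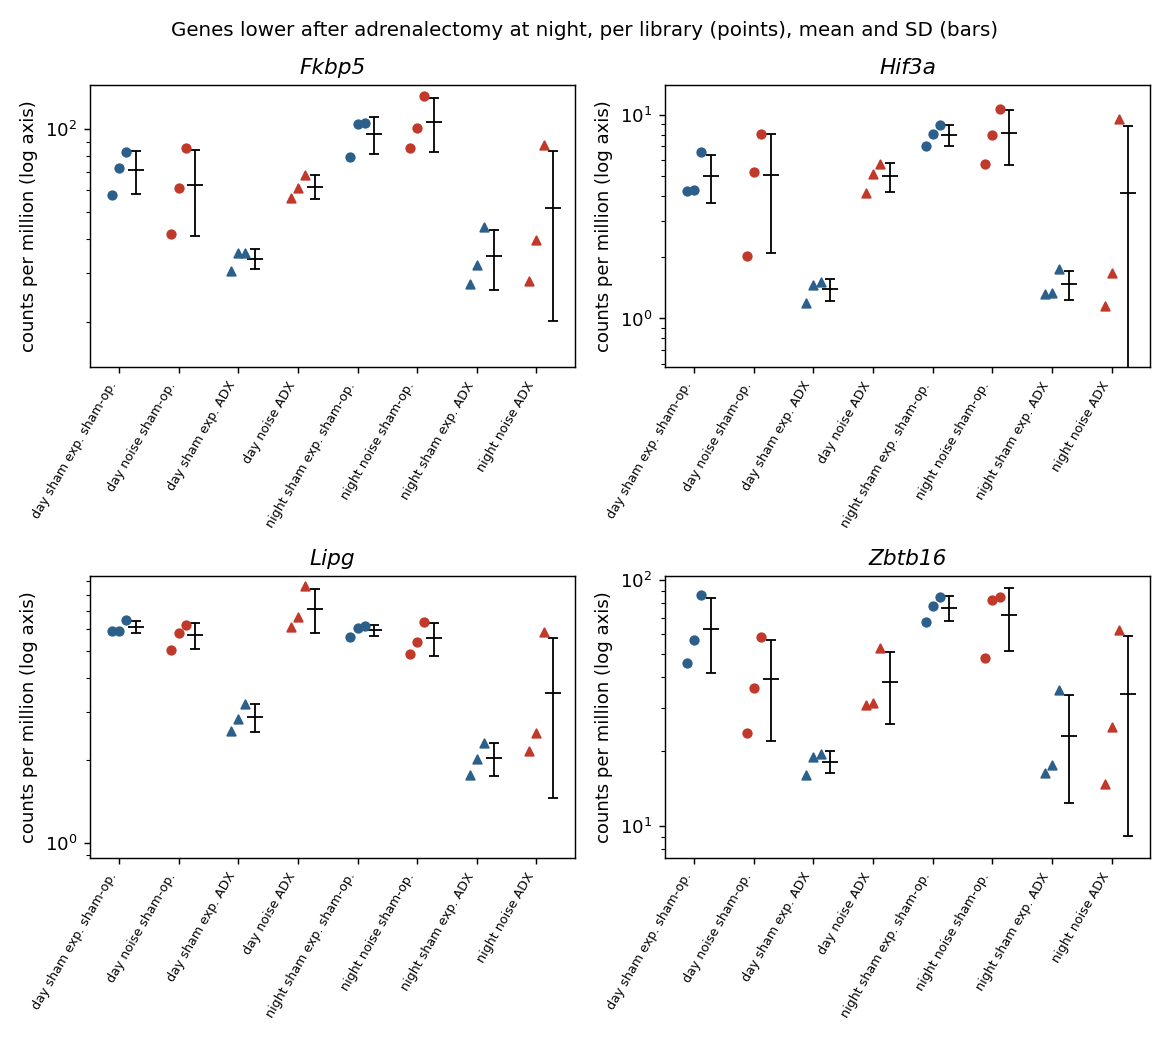
CPM (log axis) of Fkbp5, Hif3a, Lipg and Zbtb16 in each library of the 8 groups, with red for noise, blue for sham exposure, circles for sham-operated and triangles for ADX, and bars for the mean and SD of 3 libraries. Each unexposed ADX library lies below the unexposed sham-operated ones of its time, each day noise ADX library lies above the day sham exposure ADX ones (Lipg 7.14 ± 1.3 against 2.87 ± 0.326 CPM), and the Hif3a bar of night noise ADX (4.11 ± 4.68 CPM) runs off the axis.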

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

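All tests of an explanation in this part, the splits of the samples included, were chosen after the results were seen; the tests of a difference between groups were planned.

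Khdrbs3, a regulator of splicing, stands out because its response to noise differed between night and day in ADX mice. The difference was 0.60 on the log2 scale (SE 0.086, adjusted p = 0.0103), with a fall by day of -0.32 and a rise at night of 0.29. In sham-operated mice its changes were 0.06 by day and -0.03 at night, neither past the threshold. That the difference is particular to ADX was not shown. The edgeR test of noise by time by surgery called 0 genes, with a smallest adjusted p of 0.0973 over all genes. The call of Khdrbs3 rests on several libraries, since 4 of the 12 fits without 1 library ended it. Its adjusted p reached 0.076 without day sham exposure ADX a. A fit of only the groups compared called 0 genes, as did the fit without the 3 libraries with pituitary or cerebellar transcripts. The difference also uses the day noise ADX libraries, in which glucocorticoid may have been present, as described below. Of 100 splits of the samples 10 called at least as many genes as the real 1, and the highest of the other splits called 725, so chance is not excluded. Splits with that many calls hold a structure of the samples, which includes the noise effect itself where an arm is relabelled; no other structure was tested.

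Nr1d1, a repressor of the clock, stands out because its change from day to night differed between ADX and sham-operated mice. The difference was 1.58 on the log2 scale (SE 0.21, adjusted p = 0.0047). It passed without any 1 of the 12 libraries. Of 100 splits 7 called at least 1 gene, and the highest of the others called 5. These splits exchange day and night labels within a surgery, so they can hold the effect of time itself. Their share therefore leaves chance undecided for the count. Cry1, Per2 and Npas2 had smaller fitted changes in ADX too, with differences that did not pass, so a lower amplitude of the whole clock was not shown.

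Genes that differ between noise-exposed and unexposed libraries labelled day ADX tended to move against the effect of adrenalectomy. Of the 667 called, 449 (67.3%) had the sign opposite to the effect of adrenalectomy at night, against 53.5% of the genes not called, and of those called in both comparisons 26 went opposite ways and 3 the same way. Of the same 667 genes, 461 (69.1%) had the sign of the noise effect by day in sham-operated mice. The called genes thus also tended to move as with noise in sham-operated mice, though that share was not computed for the genes not called. A score over the 263 genes that adrenalectomy changed at night, high where they lie as in sham-operated mice, was 0.0643, -0.104 and -0.108 in the day noise ADX libraries. It was -0.696, -0.534 and -0.431 in day sham exposure ADX and 0.133, -0.0465 and -0.222 in day noise sham-operated. In night noise ADX, library a scored 0.399 and the others -0.183 and -0.418, with Lipg at 5.89, 2.51 and 2.16 CPM.

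An exchange of labels between day noise ADX and day noise sham-operated was not decided by the score. Of the 3 day noise sham-operated libraries 0 scored within or below the range of day sham exposure ADX. That test takes noise to leave the score of adrenalectomized mice unchanged, which was not known. The scores of both day noise groups also overlapped. Glucocorticoid present in the day noise ADX animals, through a wrong surgery label or incomplete surgery, remains a candidate explanation. Over these genes the median difference between day noise ADX and day noise sham-operated was -0.00606, against -0.301 between the unexposed groups by day. A response to noise that moves these genes in adrenalectomized mice alone cannot be told apart from it: the median noise effect by day in sham-operated mice was -0.106, and both explanations allow that value. The ratio of Pomc, a pituitary gene that glucocorticoid represses, to Gh did not settle it. It was 0.0511, 0.0799 and 0.0676 in day noise ADX and 0.0613 in night noise ADX a, against 0.643 to 0.859 in day sham exposure ADX and 0.804 in night noise ADX c. In night noise ADX b it was 0.13 and in night sham exposure ADX 0.0848 to 0.326, low as well. In sham-operated mice by day it was 0.13, 0.0541 and 0.321 with noise and 0.167, 0.464 and 0.385 with sham exposure. At night it was 0.225, 0.206 and 0.0618 with noise and 0.0397, 0.127 and 0.224 with sham exposure. The ratio rests on few counts in most libraries. The labels give no hormone level that would separate these explanations, so the surgery effects among noise-exposed libraries may not measure the loss of the adrenal glands. The noise effect by day in ADX, with its 9 rises in glucocorticoid-induced genes, may not measure noise alone. At night libraries a and b of night noise ADX scored above the night sham exposure ADX libraries (-0.823 to -0.413). These genes were chosen with the latter, so the score decides nothing about the noise effect at night.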

How the results depend on the processing

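The fit without the 3 libraries that held most of the pituitary or cerebellar transcripts was chosen after seeing the data, and it kept night noise ADX c. The other alternatives were planned. Counts of genes past the threshold count as moved where they differ from those of the report by more than 1.5 times. No named gene that was called in the report or in an alternative changed its sign in that alternative. No list that was called in both changed its direction. Changes of sign in other genes and lists were not counted. RLE size factors and no filter on low counts moved none of the 14 counts.

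DESeq2 gave more genes in all 14: for noise, 123 by day and 210 at night in sham-operated mice and 1285 and 182 in ADX; for noise by time 20 (sham-operated) and 24 (ADX); for noise by surgery 158 by day and 4 at night; for noise by time by surgery 197; for time 220 (sham-operated) and 37 (ADX); for time by surgery 11; for adrenalectomy 179 by day and 599 at night. Of the 41, 119, 667 and 83 genes called for noise by edgeR, it kept 41, 119, 658 and 82. Limma voom with library weights moved 10 counts, to 255 for noise at night in sham-operated mice and 1481 for noise by day in ADX; 14 for noise by time in sham-operated mice, 291 for noise by surgery by day and 575 for noise by time by surgery; 420 and 38 for time in sham-operated and ADX mice and 96 for time by surgery; 128 and 1262 for adrenalectomy by day and at night. It gave day noise ADX a a weight of 0.452. The cause was not tested.

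A fit of only the groups compared, which estimates the spread from fewer samples, gave 410 and 44 genes for noise by day and at night in ADX, 0 for noise by time in ADX, 12 for noise by surgery by day, 13 for time in sham-operated mice, 13 for time in ADX, 2 for time by surgery and 88 for adrenalectomy by day. The replicate block gave 22 for time in sham-operated mice. Without the 3 libraries with pituitary or cerebellar transcripts the counts were 44 for noise at night in ADX, 0 for noise by time in ADX and 73 for adrenalectomy by day, which kept 7 of its 7 genes; 3 comparisons use none of the 3 libraries in their groups and were not rerun. The cause was not tested.

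Without 1 library the counts ran from 23 to 55 and from 78 to 118 for noise by day and at night in sham-operated mice, from 144 to 2254 and from 37 to 134 in ADX. They ran from 0 to 0 for noise by time in sham-operated mice and from 0 to 36 in ADX, from 0 to 811 for noise by surgery by day and from 0 to 0 at night, and from 0 to 554 for noise by time by surgery. They ran from 6 to 105 for time in sham-operated mice, from 0 to 3 in ADX and from 1 to 2 for time by surgery, and from 0 to 30 and from 0 to 196 for adrenalectomy by day and at night. The highest counts for noise by day in ADX (2254), noise by surgery by day (811) and noise by time by surgery (554) are those without day noise ADX a. Without it 641 of the 667 genes were kept.

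Of 231 results on named genes, 225 kept their side of the threshold under DESeq2 and 5 came to pass it; 210 kept it under limma voom, 6 came to pass and 15 no longer passed. Fits of only the groups compared gave 169, 10 and 52. With the block, no filter and RLE factors 15, 8 and 1 no longer passed. Over the fits without 1 library 1012 were kept and 386 no longer passed. Without the 3 libraries 119 were kept, 1 came to pass and 27 no longer passed. Of 336 list results 132 no longer passed with an estimated correlation and 204 were kept; with the block 3 came to pass and 2 no longer did, with RLE factors 1 and 1, and without the 3 libraries 19 and 14. On simulated data 65.2% of the changes of 1.5-fold were recovered for noise at night in sham-operated mice and 24.2% for noise by time by surgery; depth was not varied, so what it limits was not tested.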

Other observations

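All tests in this part were chosen after the results were seen: those of the collection time and of pituitary tissue, the splits of the samples, and the comparisons of time and of adrenalectomy among noise-exposed mice.

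Among noise-exposed sham-operated mice 186 genes differed between night and day, 134 higher and 52 lower at night. The noradrenaline transporter Slc6a2 was higher by 1.79 (adjusted p = 0.00312), and the stress genes Gem, Ptgs2 and Gdf15 were higher by 1.25, 1.185 and 1.165. Cirbp, an RNA-binding protein induced by cold, was lower (-0.845, adjusted p = 0.00943), as was the lipase Lpl (-1.125). Adrenalectomy among noise-exposed mice gave 0 genes by edgeR by day and 0 at night, with 1950 and 1420 at an unadjusted p under 0.05. No other tool was run on this pair. Fkbp5 differed by -0.02 by day and -1.03 at night, neither past the threshold.

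Clock genes in night minus day libraries of sham-operated mice were set against the 2 collection times in the sources. Collection at the labelled circadian times is argued against: the median change of Per2, Npas2 and Arntl in the direction that ZT23 against ZT11 predicts was -0.85 among noise-exposed mice. An exchange of the day and night labels at these times is argued against as well, with Nr1d1 at -1.68. Collection 2 h after exposure remains a candidate explanation: 4 of 4 genes (Per2, Cry1, Nr1d1 and Dbp) moved as it predicts, though Dbp did not pass the threshold (-0.64, adjusted p = 0.0571). Of these 4, Per2 alone was predicted to move in opposite directions by the 2 collection times. A lower Nr1d1 at night goes with the labelled times too. The 4 genes had moved this way in unexposed mice before the prediction was written, so their count adds little. No biological explanation was tested.

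Pituitary hormone transcripts in night noise ADX libraries were highest in library a, where 7 of 7 pituitary genes had their highest value of the 24 libraries. Pituitary tissue carried into the dissection is a candidate explanation. A response of the cochlea to noise in adrenalectomized mice at night cannot be told apart by the test run, since Gh lay above the highest of the other 21 libraries in 2 of the 3. Library b had 8.7 CPM of Gh, within the range of the others, and 4 of the 7 genes passed the filter. The origin of the cerebellar transcripts in the other two libraries was not tested.

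For the comparisons of a pair of groups, the 10 splits of 6 samples are too few for a share under 0.05. The real split was the 1 with the largest count in each. The real counts and the highest of the other splits were 41 and 0, 119 and 0, 667 and 0, and 83 and 38 for the noise comparisons in the order of the report. They were 44 and 0 and 3 and 0 for time in sham-operated and ADX mice, and 7 and 0 and 263 and 1 for adrenalectomy by day and at night. For the differences with a real count of 0 by edgeR, 100 of 100 splits called at least as many, which a count of 0 fixes, so these splits say nothing about chance. The highest of the other splits called 120 for noise by time in sham-operated mice, 371 and 747 for noise by surgery by day and at night, and 542 for noise by time by surgery. Splits with that many calls hold a structure of the samples, which includes the noise effect itself where an arm is relabelled; no other structure was tested.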
